A study of Mus musculus with 15 samples.

How the data were processed

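Liver RNA from 15 samples was labelled with a 3' in vitro transcription kit and hybridised to a whole-genome Affymetrix mouse expression array. Mice were 15 weeks old at death. DEN was given once at 12 weeks of age (100 mg/kg). CCl4 (0.50 ml/kg) followed at an age of 13 weeks and again of 15 weeks, and livers were taken 48 hours after the last dose. The antibiotic group drank ampicillin, neomycin and metronidazole at 1 g/l each and vancomycin at 500 mg/l for 2 weeks from week 10. The labels also carry a description that gives other ages and mentions a liver resection, which contradicts the rest and was not used, and mutant replicate 1 has no sex given, the others being male. Its levels of the Y-linked genes Eif2s3y (11.69), Kdm5d (8.69) and Uty (7.82) lay above the highest wild-type array (11.18, 7.87 and 7.54), as did those of the other 3 mutant arrays (12.06 to 12.27, 8.28 to 8.9 and 8.14 to 8.41), and Xist was at 2.05 (1.95 to 2.39 on the other mutant arrays, 1.84 to 2.67 on wild-type ones). The labels number the arrays from 1 to 15 across the groups, and replicates are counted here in that order within each group. They name no batch, scan date or pairing.

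The deposited values are log2 GCRMA probe set summaries, background corrected and normalised between arrays by the authors. GCRMA is named without a version, and its settings are not given. The table had no missing values (0), and 0 of its columns were left unused. Values were taken as deposited for the tests. The array gives no count of molecules, so the depth behind a value is its signal over background. A log2 value under 4 was treated as close to background, and 34.6% to 36.7% of probe sets were at or above it per array. Array medians over the kept genes ran from 7.648 to 7.906.

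Probe sets were named through an annotation table and the gene table of assembly GRCm38.p6, which was used for names and for which genes are neighbours, with no coordinates. Of all probe sets, 34945 carried 1 gene symbol (18193 symbols in all), 932 several, 9160 none and 64 were controls; 204 Entrez identifiers were not in the gene table. Probe sets with several symbols or none were kept out of the tests and counted once in the closing section. Genes were kept if a probe set reached 4 on at least 3 arrays, whatever the group (15541 probe sets), and the probe set with the highest mean over all arrays stood for its gene (9482 genes). Of 3847 genes with several kept probe sets, 197 had probe sets called in both directions in treated against untreated wild type, 85 in the mutant comparison and 6 in the antibiotic comparison.

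Differences were tested with limma 3.58.1 in R 4.3.3, with 4 group means fitted to all 15 arrays (11 residual degrees of freedom, prior degrees of freedom 3.4, prior SD 0.203) and a Benjamini-Hochberg adjusted p under 0.05 within each of 6 comparisons. A gene called changed, higher or lower passed that threshold. Where all arrays of the lower group were under 4, the fold was bounded from a floor of 4. After the values were seen this was extended to groups with some arrays under 4, those arrays being set to 4. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

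The comparisons, the alternatives, the rule for named genes and 35 gene lists (928 entries, 837 on the array) were fixed before the data were examined. The lists cover inflammation, cell division and death, growth factors, cell types of the liver, hepatocyte zones, metabolism, stress, the circadian clock and sex-biased genes. Lists of cell type markers included neutrophils, T and NK cells, B cells, pancreas, adipose tissue and erythroid cells. Lists with at least 5 kept members were tested with limma's camera at a preset correlation between genes of 0.01, with the Benjamini-Hochberg adjustment over lists, and again with an estimated correlation and with fry. Named genes were the 5 highest and 5 lowest changes without overlap between arrays in each of the first 3 comparisons, up to 3 called members with the largest changes per list, and a fixed set of 15 genes (Tlr4, Ereg, Hgf, Tnf, Il1b, Il6, Cdkn1a, Ccnd1, Mki67, Cyp2e1, Glul, Col1a1, Acta2, Timp1 and Afp). Genes with near-identical copies, such as the Mup, Saa1 and Saa2, Cyp2a, Cyp2c, Cyp3a, Hbb and immunoglobulin genes, are open to cross-hybridisation.

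The mutant and antibiotic effects share the treated wild-type arrays. Their overlap and their relation to the treatment effect were therefore set against 100 simulations of unchanged groups and recomputed over the 6 ways to divide those 4 arrays. The simulations drew each gene independently, with no difference between any groups. Alternatives were centring or quantile normalising the arrays, values under 4 set to 4, no filter or a filter at 6, the mean of a gene's probe sets or every probe set on its own, array weights, a fit of only the 2 groups compared, a trended and robust prior, stricter thresholds, and leaving out each array in turn. Arrays were also regrouped in every way of the same sizes for each comparison.

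The procedure was tested on simulated data with 200 of 9482 genes changed. In the treated against untreated design, 25.4%, 68.7% and 93.9% of genes with true log2 changes of 0.5, 1 and 2 were recovered, with 4 false among 129 calls. In the mutant design the shares were 26.9%, 79.1% and 93.9% (5 false of 138 calls), and in the antibiotic design 29.9%, 85.1% and 100% (9 false of 152 calls). In the list test on simulated data, a list shifted by 0.5 was called, and so was 1 of 27 lists that were not shifted. These simulated genes were drawn independently, whereas members of real lists vary together (estimated correlation 0.778 for mitosis genes). The list test was therefore not checked for such lists. The simulations also changed a far smaller share of genes than was called between treated and untreated wild type (62.6%), which affects the adjusted threshold. Strain and Tlr4 genotype could not be separated, since the 2 differ together in every array, and without untreated mutant liver a difference present before treatment could not be separated from the response to it. The mutation alters the protein rather than the transcript, so Tlr4 levels do not check the labels.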

Results

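Transcript levels were measured in 15 liver samples, 1 array each. Wild type for Tlr4, the receptor for bacterial lipopolysaccharide, was the C3H/HeOuJ strain, and the mutant was the related C3H/HeJ strain, whose Tlr4 carries a point mutation that blocks signalling. The groups were untreated wild-type mice (3 arrays), wild-type mice given diethylnitrosamine (DEN, a liver carcinogen) and carbon tetrachloride (CCl4, a liver toxin) (4 arrays, called treated wild type), mutant mice given the same (4 arrays, treated mutant), and wild-type mice given antibiotics in the drinking water before the same treatment (4 arrays, antibiotic group). The series concerns the part that gut bacteria and Tlr4 play in promoting hepatocellular carcinoma. Levels are log2 GCRMA values, given as mean ± SD with n = 3 untreated arrays and n = 4 in each other group, and differences are log2 fold changes ± SE with an adjusted p. The number of arrays limits the precision, and each p of a single gene measures the spread between arrays of different samples. A camera p sets a list against the other genes at the preset correlation, and a permutation p shuffles genes. Neither of these measures that spread directly.

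Between 34.6% and 36.7% of the array's probe sets reached a log2 value of 4, and 9482 genes entered the tests. Correlations between arrays of a group over these genes ranged from 0.977 to 0.993. Tlr4 itself was below the detection filter on all arrays (1.84 to 3.67), as were the epidermal growth factor receptor ligand Ereg (2.28 to 3.98) and the inflammatory cytokines Tnf (1.9 to 2.56), Il1b (2.55 to 2.92) and Il6 (1.3 to 1.74), so none of these 5 was compared. Levels below 4 are close to background. Where arrays of the lower group were under 4, they were set to 4 and the fold is given as a lower bound, while log2 differences are those of the deposited values. For the gene lists, counts of members that rose or fell are over all genes tested, with the count adjusted over the list alone beside them wherever it differs. Scaling mattered for the balance of directions. Centring each array on its median moved the median change over all genes from 0.101 to -0.122 in treated against untreated wild type, from 0.106 to -0.071 in the antibiotic group against untreated, and from 0.128 to -0.052 in the mutant against untreated.

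The first comparison asks what DEN and CCl4 did to the wild-type liver. Genes of dividing cells went from background to high levels. Mki67, a nuclear protein of proliferating cells, rose from 2.64 ± 0.05 to 11.25 ± 0.37, at least 152-fold (adjusted p = 1.28e-09), and Top2a, a topoisomerase needed to separate chromosomes, rose from 2.47 ± 0.05 to 10.68 ± 0.22, at least 102-fold. Cdkn1a, a p53 target that inhibits the cell cycle, rose at least 97.6-fold to 10.61 ± 0.63. The fetal liver protein Afp rose 183-fold, from 4.78 ± 0.71 to 12.3 ± 0.7. At the other end, the pericentral enzymes Cyp2e1, which activates CCl4, and Glul, which makes glutamine, fell 9.89-fold and 9.81-fold, from 14.33 ± 0.09 to 11.02 ± 0.69 and from 12.46 ± 0.1 to 9.17 ± 0.26.

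In all, 5938 of 9482 genes changed, 3408 higher and 2530 lower (57.4% higher, but 42.4% with each array centred and 43.8% after quantile normalization). At least 2-fold changes numbered 1731 higher and 933 lower. The treated and untreated arrays did not overlap for 6295 genes (66.4%, against 5.7% by chance). The genes named next had the 5 highest and 5 lowest log2 differences, which have no certain order where they are measured against background. Besides Mki67, Top2a and Cdkn1a, the highest were in Lgals3, a galectin of macrophages and injured tissue (8.12 ± 0.37, at least 188-fold), and Uhrf1, which maintains DNA methylation at replication (at least 131-fold). The lowest were in Dio1, which activates thyroid hormone (-6.25 ± 0.52, at least 37.7-fold), the potassium channel gene Kcnk1 (at least 20.5-fold), Adgrv1 (at least 33.2-fold), Rgs16, a brake on G protein signalling (-5.82 ± 1.16, at least 39.7-fold), and the cell death gene Bmf (at least 36.9-fold). Above 4 in both groups, Cyp2c37 fell 45.8-fold.

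All 39 measured genes of the mitosis and G2/M list rose (39 adjusted over the list alone). The mitosis median was 5.85, or 4.58 with values under 4 set to 4 (camera adjusted p = 2.49e-16; adjusted p = 0.194 with an estimated correlation). Of 39 DNA replication and S phase genes, 38 rose and 1 fell (38 and 1 adjusted over the list alone), among them Rrm2, a subunit of the enzyme that makes deoxynucleotides (7.64 ± 0.26), and Mcm5 of the replicative helicase (7.48 ± 0.24). Their median was 4.11, or 4.06 from the floor (camera adjusted p = 1.18e-17; adjusted p = 0.148 with an estimated correlation). Among 21 p53 targets, 15 rose and 1 fell (15 and 2 adjusted over the list alone), including Psrc1 and Phlda3. The p53 target median was 1.66, or 1.32 from the floor (camera adjusted p = 0.00261; adjusted p = 0.311 with an estimated correlation). The cell cycle regulator Ccnd1 rose 12.7-fold, and 12 of 13 oncofetal and hepatocellular carcinoma markers rose while 1 fell (12 and 1 adjusted over the list alone), including Ly6d and the adhesion receptor Cd44 (median 3.67, camera adjusted p = 1.84e-05; adjusted p = 0.107 with an estimated correlation).

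Genes of cells other than hepatocytes rose as well. Of 32 extracellular matrix and stellate cell genes, 31 rose (31 adjusted over the list alone). The matrix median was 2.5, or 1.96 from the floor (camera adjusted p = 5.54e-10; adjusted p = 0.148 with an estimated correlation). Acta2, the smooth muscle actin of activated stellate cells, rose 34.8-fold, from 5.22 ± 0.23 to 10.34 ± 0.39. The collagen gene Col1a1 rose at least 9.68-fold and Timp1, an inhibitor of matrix proteases, at least 2.65-fold. Of 16 Kupffer cell and macrophage genes, 14 rose (14 adjusted over the list alone), including the lysosomal protein Cd68 (2.86 to 9.29) and the signalling adaptor Tyrobp (4.38 ± 0.41). The macrophage median was 2.68 (camera adjusted p = 5.33e-06; adjusted p = 0.194 with an estimated correlation). All 17 monocyte-derived and scar-associated macrophage genes rose (17 adjusted over the list alone), among them S100a6 (6.16 ± 0.28). The monocyte-derived macrophage median was 3.29, or 2.49 from the floor (camera adjusted p = 3.13e-07; adjusted p = 0.135 with an estimated correlation). Hgf, a hepatocyte growth factor made by stellate and endothelial cells, rose 2.91-fold, from 5.14 ± 0.24 to 6.68 ± 0.21.

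Of 17 sinusoidal endothelial genes, 9 rose (9 adjusted over the list alone), including the hyaluronan receptor Lyve1 (2.89 ± 0.38) and the scavenger receptor Stab1 (1.26 ± 0.18). The endothelial median was 0.8 (camera adjusted p = 0.0393; adjusted p = 0.631 with an estimated correlation). That call ended without untreated replicate 1 (median 0.35, adjusted p = 0.173), without treated wild-type replicates 1 (0.058) or 3 (0.0642), after quantile normalization (0.0661), and with the fit held to both groups alone (0.0595). Of 9 cholangiocyte and progenitor genes, 6 rose (6 adjusted over the list alone), including Anxa3 and Prom1. The cholangiocyte median was 1.27 (camera adjusted p = 0.0131; adjusted p = 0.148 with an estimated correlation). With values under 4 set to 4 the median was 0.65 and the adjusted p 0.0781, and after quantile normalization they were 0.46 and 0.0578. All 4 measured MHC class II genes rose, including H2-Aa (1.26 ± 0.22), although quantile normalization ended the call of H2-Ab1 (0.88, then 0.28 with an adjusted p of 0.173). Of 3 neutrophil genes 2 rose (3 adjusted over the list alone), the calcium-binding proteins S100a8 and S100a9. Among 2 B cell genes the immunoglobulin gene Ighm fell (-4.4 ± 0.27) and Bank1 rose, although the Bank1 call ended with values under 4 set to 4 (adjusted p = 0.166) and after quantile normalization (0.0532). No T or NK cell gene passed the detection filter.

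Hepatocyte programmes moved down. Of 21 pericentral genes, 18 fell and 1 rose (18 and 1 adjusted over the list alone). The pericentral median was -2.04 (camera adjusted p = 6.25e-07; adjusted p = 0.107 with an estimated correlation), and Cyp2c37 fell from 10.84 to 5.32. Of 27 cytochrome P450 genes, 19 fell and 2 rose (19 and 2 adjusted over the list alone; median -1.21, camera adjusted p = 8.77e-07; adjusted p = 0.135 with an estimated correlation). Several Cyp2c, Cyp2a and Cyp3a genes have near-identical copies, and their probe sets are open to cross-hybridisation. Of 23 hepatocyte identity genes, 15 fell and none rose (15 adjusted over the list alone), including Gnmt, a methyltransferase of methionine metabolism (-2.09 ± 0.25), and Otc of the urea cycle (-1.43 ± 0.17). The identity gene median was -0.61 (camera adjusted p = 1.78e-05; adjusted p = 0.148 with an estimated correlation). Of 19 periportal genes 9 fell and 2 rose (9 and 2 adjusted over the list alone; median -0.46, camera adjusted p = 0.0131; adjusted p = 0.311 with an estimated correlation), and quantile normalization ended this call (0.318). All 16 male-biased genes fell (16 adjusted over the list alone), among them complement C6 and the fatty acid elongase Elovl3 (-3.25 ± 0.62; median -1.66, camera adjusted p = 1.31e-06; adjusted p = 0.157 with an estimated correlation).

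Bile acid, cholesterol, lipogenesis and circadian lists also held more members that fell than rose. Of 29 bile acid genes, 20 fell and 4 rose (21 and 5 adjusted over the list alone), including Cyp7a1, the rate-limiting enzyme of bile acid synthesis (-2.47 ± 0.56), and the uptake carrier Slco1a1 (-4.79 ± 0.67). The bile acid gene median was -0.87 (camera adjusted p = 8.51e-05; adjusted p = 0.107 with an estimated correlation). Among 20 cholesterol biosynthesis genes 11 fell (11 adjusted over the list alone), Tm7sf2 the most (-2.53 ± 0.18; median -0.64, camera adjusted p = 0.000938; adjusted p = 0.444 with an estimated correlation). Among 23 lipogenesis genes 14 fell and 1, the fatty acid carrier Cd36, rose (4.85 ± 0.62), with the same counts adjusted over the list alone (median -0.56, camera adjusted p = 0.00111; adjusted p = 0.148 with an estimated correlation). In the circadian list of 17 genes, 10 fell and 1 rose (10 and 1 adjusted over the list alone), including Per3 (-1.56 ± 0.29) and, upward, Clock (1.35 ± 0.14; median -0.67, camera adjusted p = 0.0135; adjusted p = 0.157 with an estimated correlation).

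Of 28 lists large enough to test, 18 passed the camera test in this comparison and 0 did with an estimated correlation. The others held members that moved both ways. NF-kB target cytokines and chemokines had 5 of 14 members higher and 2 lower (camera adjusted p = 0.543), among them the adhesion molecules Vcam1 (3.34 ± 0.32) and Icam1 (1.71 ± 0.21). TLR4 signalling and pattern recognition genes had 5 of 18 higher and 4 lower (4 and 4 adjusted over the list alone; 0.815), with the lipopolysaccharide co-receptor Cd14 rising from 2.58 to 7.79. Acute-phase proteins had 5 of 28 higher and 5 lower (4 and 5 adjusted over the list alone; 0.768), Lcn2 rising by 6.86 ± 0.64. Interferon-stimulated genes had 12 of 30 higher and 7 lower (0.657), apoptosis regulators 8 of 24 higher and 11 lower (0.366), growth factors and EGF receptor ligands 9 of 17 higher and 6 lower (0.767), and NRF2 targets 8 of 27 higher and 12 lower (0.184). Fatty acid oxidation genes had 6 of 31 higher and 10 lower (5 and 10 adjusted over the list alone; 0.36), with a median of -0.01 and a mean of 0.26. Unfolded protein response genes had 11 of 25 higher and 4 lower (0.341), with the serine synthesis enzyme Psat1 rising from 3.01 to 9.12, and female-biased genes 4 of 10 higher and 2 lower (0.926). With no filter the NF-kB (0.0492) and unfolded protein response (0.0388) lists passed. The fry test, which does not compare a list with other genes, called NF-kB targets (9.55e-05), TLR4 signalling (0.0175), interferon-stimulated genes (0.0291), apoptosis regulators (0.000799), growth factors (0.00114), NRF2 targets (0.0321) and the unfolded protein response (0.000335). Of the pancreas list 1 of 2 genes rose and 1 fell, of the adipose list 1 of 2 rose (1 rose and 1 fell adjusted over the list alone), and of the erythroid list 1 of 4 rose and 2 fell.

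**Figure D1:**
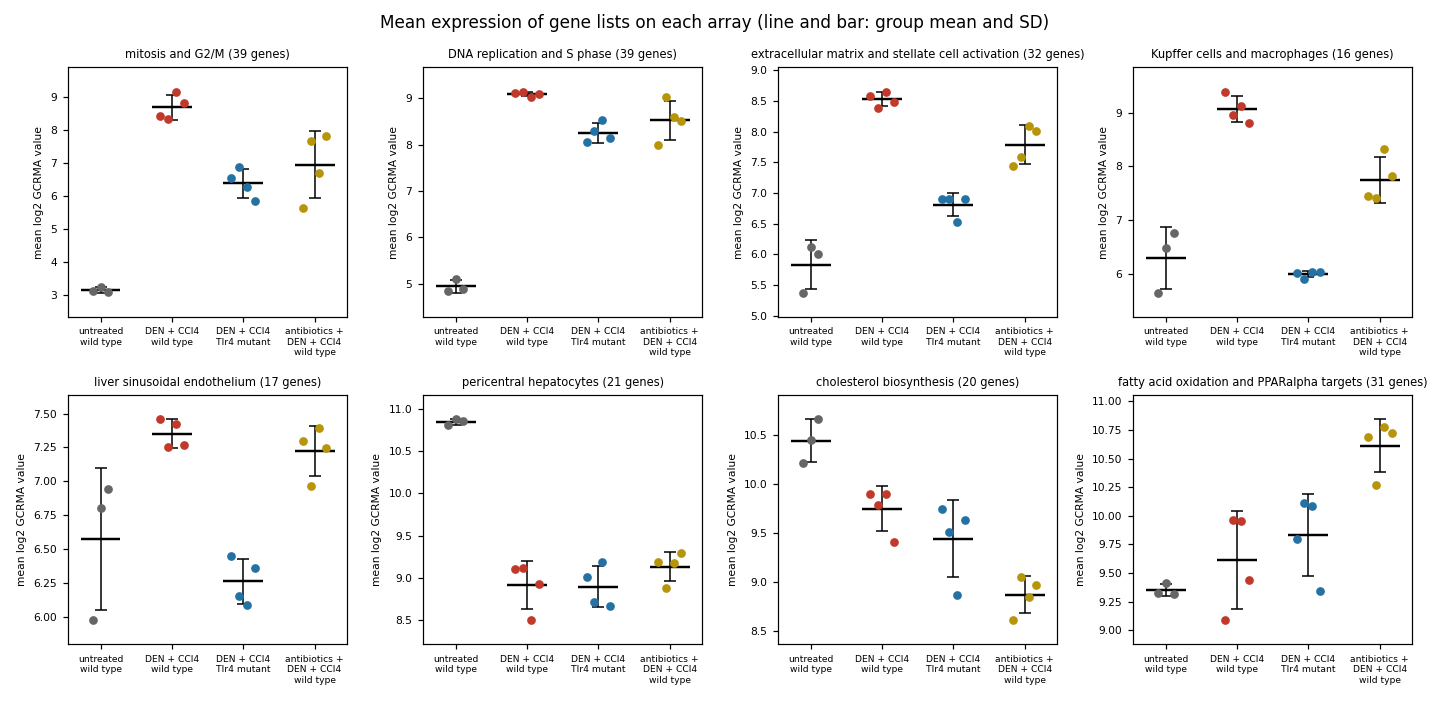
Mean log2 GCRMA value of each gene list (vertical axis) on each of the 15 arrays (points), by group (horizontal axis), with a line and bar for the group mean and SD. Mitosis means lay at 3.09 to 3.24 in untreated, 8.32 to 9.15 in treated wild-type, 5.82 to 6.86 in treated mutant and 5.61 to 7.8 in antibiotic arrays, while endothelial means lay at 6.09 to 6.45 in the mutant and 6.96 to 7.39 in the antibiotic group.

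The second comparison sets treated mutant against treated wild-type mice and asks what loss of Tlr4 function changed; strain and mutation differ together, since the mutant is another C3H substrain. Macrophage genes were far lower in the mutant. Vsig4, a complement receptor of Kupffer cells, fell at least 40.7-fold, from 9.36 ± 0.46 to 3.77 ± 0.23 (adjusted p = 1.26e-06), and Tyrobp fell 17.9-fold, from 9.73 ± 0.31 to 5.57 ± 0.24. Hgf fell at least 4.58-fold, from 6.68 ± 0.21 to 4.45 ± 0.48, Acta2 fell 4.39-fold, and Mki67 fell 4.65-fold, from 11.25 ± 0.37 to 9.03 ± 0.63. Cyp2e1 (-0.22 ± 0.32, adjusted p = 0.643) and Ccnd1 (-0.1 ± 0.25, 0.806) were not called, and Glul fell a further 1.66-fold.

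In all, 2917 genes changed, 1249 higher and 1668 lower (42.8% higher, but 50.5% with each array centred and 55.3% after quantile normalization). At least 2-fold changes numbered 188 higher and 746 lower. The arrays of the 2 groups did not overlap for 2946 genes (31.1%, against 2.9% by chance). The 5 highest log2 differences, again without certain order against background, were in Sprr1b, a cornified envelope protein (at least 7.81-fold, 6.97 ± 1.28 in the mutant), the ion cotransporter gene Slc12a4 (at least 4.42-fold, 6.14 ± 0.32), Sfmbt2 (at least 2.82-fold), Csad, an enzyme of taurine synthesis (9.55-fold), and Atp13a4 (at least 4.42-fold). Next to Vsig4 and Tyrobp, the lowest were in the interferon-inducible genes Mndal (at least 27.8-fold, 3.88 ± 1.8 in the mutant) and Ifi202b (at least 6.7-fold) and in B3galnt1, a glycosyltransferase (at least 6.36-fold). The arrays behind Mndal disagreed, with 1 mutant array at 6.58 and the others at 2.87 to 3.15. Above 4 in both groups, the serine synthesis enzyme Phgdh rose 8.74-fold and the kinase Aurkb fell 13.1-fold.

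Of 16 Kupffer cell and macrophage genes, 15 fell in the mutant and none rose (15 adjusted over the list alone), including the haemoglobin scavenger receptor Cd163 (7.31 to 3.21). The macrophage median was -3.08 (camera adjusted p = 4.84e-16; adjusted p = 0.145 with an estimated correlation). Of 17 monocyte-derived macrophage genes, 13 fell and 1 rose (13 and 3 adjusted over the list alone), including the chemokine receptor Ccr2 and lysozyme Lyz2 (-2.65 ± 0.44). The monocyte-derived macrophage median was -1.71, or -1.58 from the floor (camera adjusted p = 1.27e-05; adjusted p = 0.326 with an estimated correlation). Of 32 matrix and stellate cell genes, 28 fell and none rose (29 adjusted over the list alone), among them the collagens Col5a2 (-3.2 ± 0.27) and Col6a3 (-3.22 ± 0.31) and Col1a1 (at least 5.32-fold, from 7.28 ± 0.54 to 4.79 ± 0.91). The matrix median was -1.7, or -1.51 from the floor (camera adjusted p = 5.04e-17; adjusted p = 0.145 with an estimated correlation). Timp1 fell at least 2.65-fold. Of 17 sinusoidal endothelial genes, 16 fell (16 adjusted over the list alone), including Lyve1 (-1.95 ± 0.35) and the mannose receptor Mrc1 (-1.76 ± 0.23). The endothelial median was -1.01 (camera adjusted p = 1.27e-08; adjusted p = 0.352 with an estimated correlation). All 4 MHC class II genes fell, including the invariant chain Cd74 (-1.39 ± 0.24), as did 2 of 3 neutrophil genes and both B cell genes, Ighm being open to cross-hybridisation. With values under 4 set to 4 both B cell calls ended (Bank1 -0.63, adjusted p = 0.196; Ighm -0.24, 0.308).

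Cell cycle genes were lower together. Of 39 mitosis genes, 38 fell (39 adjusted over the list alone), including the kinase Aurkb (8.66 to 4.95) and the spindle motor Kif20a (8.58 to 5.11). The mitosis median was -2.22 (camera adjusted p = 3.28e-18; adjusted p = 0.352 with an estimated correlation). Of 39 replication genes, 26 fell and 1 rose (30 and 1 adjusted over the list alone), including Rrm2 (-1.69 ± 0.24). The replication median was -0.84 (camera adjusted p = 1.48e-09; adjusted p = 0.354 with an estimated correlation). Of 21 p53 targets, 11 fell (14 adjusted over the list alone), including Psrc1 (-2.56 ± 0.32) and Phlda3 (-2.14 ± 0.38). The p53 target median was -0.65 (camera adjusted p = 0.000118; adjusted p = 0.352 with an estimated correlation). Cdkn1a fell 2.08-fold (adjusted p = 0.0247), a call that ended without mutant replicates 1 (0.0808) or 2 (0.0737) and without treated wild-type replicates 1 (0.0739) or 4 (0.0516). Of 13 oncofetal markers, 8 fell and 1 rose (11 and 1 adjusted over the list alone), including Ly6d (-2.72 ± 0.54) and the aldo-keto reductase Akr1b8 (-2.19 ± 0.24). The oncofetal marker median was -1.21 (camera adjusted p = 0.000192; adjusted p = 0.145 with an estimated correlation). Afp was -0.82 ± 0.32 (adjusted p = 0.0699), and it passed the threshold without treated wild-type replicate 3 (-1.09, 0.0171), without untreated replicate 1 (0.0378), with arrays weighted (0.0457) and with probe sets averaged (0.0454).

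Some stress genes rose in the mutant. Of 27 NRF2 targets and glutathione genes, 9 rose and 2 fell (9 and 2 adjusted over the list alone), including the efflux pump Abcc4 (2.11 ± 0.4) and the carbonyl reductase Cbr1 (1.17 ± 0.23). The NRF2 target median was 0.34 (camera adjusted p = 0.002; adjusted p = 0.354 with an estimated correlation). Of 25 unfolded protein and integrated stress response genes, 8 rose and 1 fell (10 and 1 adjusted over the list alone). The stress response median was 0.21 (camera adjusted p = 0.00205; adjusted p = 0.354 with an estimated correlation). Phgdh, the first enzyme of serine synthesis, rose from 6.09 to 9.22, and the stress kinase homologue Trib3 rose by 1.73 ± 0.3. Among 17 growth factor genes, Hbegf, an EGF receptor ligand, rose from 4.3 to 7.4 (3.11 ± 0.37), while Hgf and Rspo3, a Wnt enhancer of endothelial cells (-1.64 ± 0.22), fell; 2 rose and 6 fell in all (camera adjusted p = 0.171, but 0.0224 with no filter and 0.0012 with fry).

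In the mutant 10 of 28 lists passed the camera test, 0 with an estimated correlation, and the inflammatory lists were not among them. NF-kB targets had 0 of 14 higher and 2 lower, Vcam1 (-2.03 ± 0.3) and Csf1, a macrophage growth factor (-0.8 ± 0.21; camera adjusted p = 0.984 for the list). TLR4 signalling genes had 5 of 18 higher and 2 lower (0.07), a p that was 0.0142 under a stricter detection filter, 0.0284 with values under 4 set to 4 and 0.0263 with fry. Of the 5 higher, Ikbkg (0.74) turned to -0.31 with probe sets averaged (adjusted p = 0.18). Acute-phase proteins had 1 of 28 higher and 3 lower (1 and 0 adjusted over the list alone; 0.796), and interferon-stimulated genes 4 of 30 higher and 11 lower (5 and 11 adjusted over the list alone; 0.312), including Ifit2 (-2.67 ± 0.35) and Oas1a (-1.72 ± 0.28). Hepatocyte lists did not pass with all arrays: 1 of 23 identity genes rose (0 adjusted over the list alone; 0.0668), 1 of 21 pericentral genes rose and 3 fell (0 and 3 adjusted over the list alone; 0.854), 2 of 19 periportal genes rose and 3 fell (0.557), and 6 of 27 cytochrome P450 genes rose and 6 fell (6 and 8 adjusted over the list alone; 0.984). The identity list passed without treated wild-type replicates 1 (0.0282) or 4 (0.0294) and with no filter (0.0444).

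**Figure D2:**
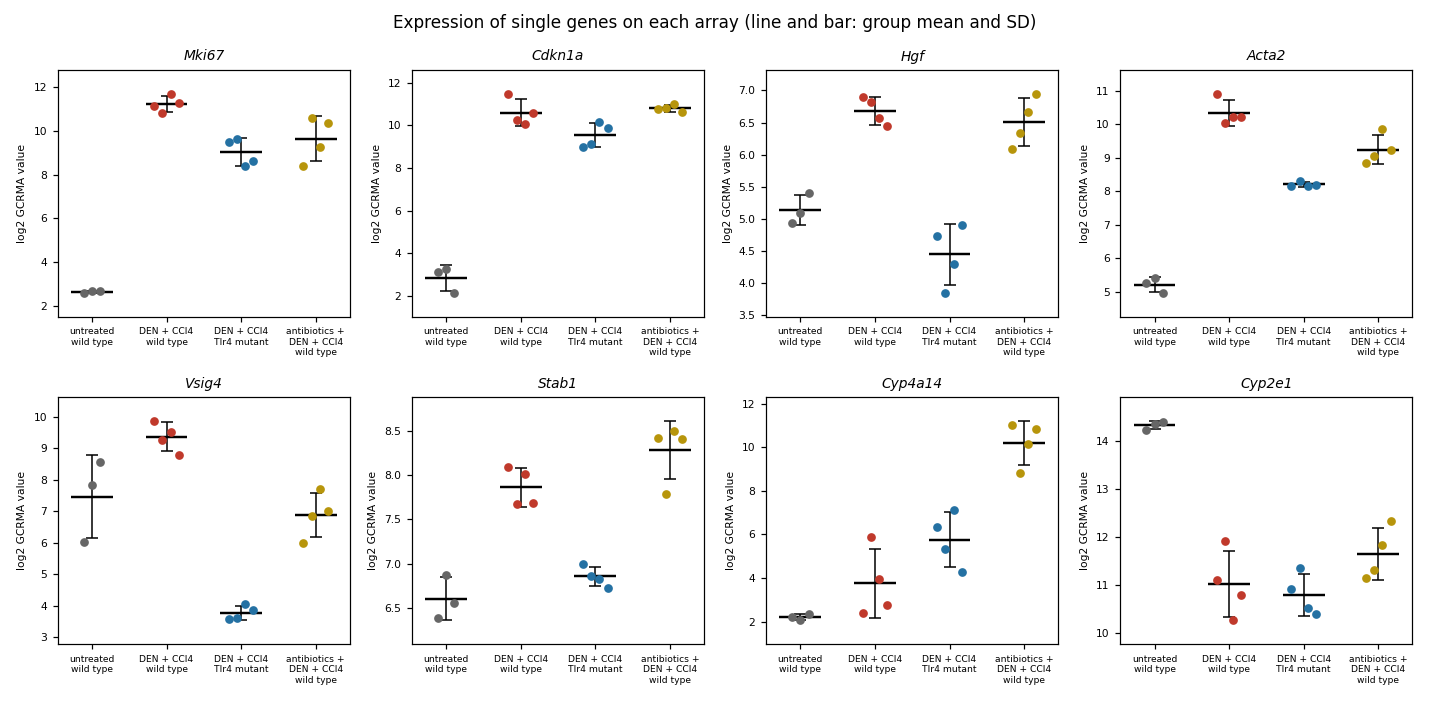
Log2 GCRMA value (vertical axis) of 8 named genes on each of the 15 arrays (points), by group (horizontal axis), with a line and bar for the group mean and SD. Hgf lay at 6.44 to 6.9 in treated wild-type, 3.85 to 4.91 in treated mutant and 6.09 to 6.95 in antibiotic arrays, and Cyp4a14 at 8.81 to 11.02 in antibiotic arrays against 2.38 to 5.89 in treated wild-type ones.

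The third comparison sets the antibiotic group against treated wild-type mice of the same strain and asks what antibiotics given before the treatment changed; bacteria were not measured here. The highest log2 difference was in Cyp4a14, a fatty acid hydroxylase induced by PPARalpha, which went from 3.75 ± 1.58 to 10.21 ± 1, or at least 53.2-fold (adjusted p = 0.000401). G6pc, the last enzyme of glucose release, rose 8.18-fold, from 8.45 ± 1.04 to 11.48 ± 0.6. Macrophage and mitosis genes were lower: Vsig4 fell from 9.36 ± 0.46 to 6.89 ± 0.7 (-2.47 ± 0.45), the macrophage surface protein Adgre1 fell by 2.36 on the log2 scale, from 7.3 to 4.94, and Kif20a fell at least 6.77-fold, from 8.58 ± 0.6 to 5.76 ± 1.67. Hgf (-0.17 ± 0.23, adjusted p = 0.671), Cdkn1a (0.2 ± 0.33, 0.741), Ccnd1 (-0.13 ± 0.25, 0.78), Afp (0.06 ± 0.32, 0.926), Cyp2e1 (0.63 ± 0.32, 0.21) and Glul (0.25 ± 0.18, 0.395) were not called.

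In all, 1323 genes changed, 469 higher and 854 lower (35.4% higher, but 45.6% with each array centred and 49.8% after quantile normalization). The count was 820 without antibiotic replicate 1 and 838 without treated wild-type replicate 4. At least 2-fold changes numbered 85 higher and 323 lower, and the arrays did not overlap for 1712 genes (18.1%, against 2.9% by chance). The other highest log2 differences were in the sulfotransferase Sult1e1 (at least 12.2-fold), the acyl-CoA thioesterase Acot3 (at least 7.91-fold) and the lipid transporter Mfsd2a (8.36-fold, a call that ended without antibiotic replicate 1, adjusted p = 0.0554, or treated wild-type replicate 4, 0.0529). The lowest were in Cyp2c55 (7.37-fold), Ugt2b38 (at least 6.58-fold), Kif20a, Cyp1a1 (at least 5.37-fold) and the spindle protein Hmmr (6.45-fold). The Ugt2b38 call (adjusted p = 0.0445) ended without any 1 of 11 arrays (up to 0.119, without antibiotic replicate 1), and held only without antibiotic replicate 3 or mutant replicates 1, 2 or 4. It also ended with no filter (0.0621) and with values under 4 set to 4 (0.0513). That of Cyp1a1 (0.0255) ended without antibiotic replicates 3 (0.058) or 4 (0.0634) and treated wild-type replicates 2 (0.0755) or 4 (0.0771).

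Of 31 fatty acid oxidation and PPARalpha target genes, 17 rose and none fell (23 adjusted over the list alone). The fatty acid oxidation median was 0.61 (camera adjusted p = 2.6e-13; adjusted p = 0.454 with an estimated correlation). Of 20 cholesterol biosynthesis genes, 12 fell and none rose (18 adjusted over the list alone), including Insig1, a sterol sensor partner (-1.53 ± 0.19), and Msmo1 (-1.42 ± 0.31). The cholesterol gene median was -1 (camera adjusted p = 2.46e-09; adjusted p = 0.454 with an estimated correlation). The fatty acid synthase gene Fasn (-1.63 ± 0.34) and Acly, which supplies acetyl-CoA (-1 ± 0.19), fell within a lipogenesis list that did not pass (5 of 23 lower and 2 higher, 6 and 2 adjusted over the list alone; camera adjusted p = 0.664). Nr0b2, a repressor of bile acid synthesis, rose by 2.3 ± 0.36 and Cyp7b1 of the alternative bile acid pathway fell (-1.61 ± 0.26), among 1 of 29 bile acid genes higher and 3 lower (0.227). Of 16 male-biased genes 7 fell and none rose (7 adjusted over the list alone; median -0.99, camera adjusted p = 3.9e-05; adjusted p = 0.454 with an estimated correlation).

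Of 39 mitosis genes, 36 fell (39 adjusted over the list alone). The mitosis median was -1.65 (camera adjusted p = 1.59e-19; adjusted p = 0.454 with an estimated correlation). Mki67 fell 3.02-fold (adjusted p = 0.0203), a call that ended without antibiotic replicates 1 (0.0516) or 3 (0.0551), without treated wild-type replicate 3 (0.0558) and with the fit held to both groups alone (0.0532). Of 39 replication genes, 9 fell (19 adjusted over the list alone), including Rrm2 (-1 ± 0.24). The replication median was -0.59 (camera adjusted p = 9.19e-08; adjusted p = 0.454 with an estimated correlation). Of 16 macrophage genes, 14 fell and none rose (15 and 1 adjusted over the list alone). The macrophage median was -1.33 (camera adjusted p = 2.26e-09; adjusted p = 0.454 with an estimated correlation). Of 17 monocyte-derived macrophage genes, 8 fell, Ccr2 among them (-1.24 ± 0.22), and 1, S100a6, rose (1.26 ± 0.26; 10 and 2 adjusted over the list alone). The monocyte-derived macrophage median was -1.07, or -0.81 from the floor (camera adjusted p = 0.00532; adjusted p = 0.454 with an estimated correlation). A stricter detection filter ended that call (0.195).

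Of 32 matrix and stellate cell genes, 16 fell and none rose (19 and 1 adjusted over the list alone), including Col5a2 (-2 ± 0.27) and Col6a3 (-1.71 ± 0.31). The matrix median was -0.74, or -0.61 from the floor (camera adjusted p = 2.13e-07; adjusted p = 0.454 with an estimated correlation). Acta2 fell 2.14-fold, from 10.34 ± 0.39 to 9.24 ± 0.43. Col1a1 fell 2.56-fold (adjusted p = 0.0428), a call that ended without any 1 of 8 arrays, which were antibiotic replicates 1 (0.126), 2 (0.063) and 4 (0.0531), treated wild-type replicates 2 (0.0878), 3 (0.11) and 4 (0.0905) and untreated replicates 2 (0.0546) and 3 (0.0513), and with no detection filter (0.0589). Timp1 fell at least 2.22-fold (0.0271), a call that ended without antibiotic replicates 1 (0.0844) or 2 (0.0513) and treated wild-type replicates 1 (0.0638) or 3 (0.0777). Only 1 of 17 endothelial genes was called, Tek (-0.75 ± 0.17; camera adjusted p = 0.653 for the list), and 0 of 4 MHC class II genes, with Cd74 at -0.37 ± 0.24 (adjusted p = 0.33). S100a8 and S100a9 fell among 3 neutrophil genes.

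Hepatocyte identity genes, with 2 of 23 higher and none lower (2 adjusted over the list alone), had a median of 0.13 (camera adjusted p = 0.00293; adjusted p = 0.454 with an estimated correlation), and quantile normalization ended the call (0.0638). Periportal genes passed with 2 of 19 higher and 1 lower (4 and 2 adjusted over the list alone, camera adjusted p = 0.045, or 0.543 with an estimated correlation). Female-biased genes passed with 3 of 10 higher and 1 lower (camera adjusted p = 0.0473, or 0.454 with an estimated correlation). Of 24 alternatives other than the estimated correlation and fry, 11 ended the periportal call and 12 the female-biased call, with adjusted p up to 0.202 and 0.179. The fry test gave 0.157 and 0.0474. The arrays that ended the periportal call when left out were antibiotic replicates 2 (0.133) and 4 (0.129), treated wild-type replicate 2 (0.139), mutant replicates 1 (0.0514) and 3 (0.052) and untreated replicate 3 (0.0505). For the female-biased list they were antibiotic replicate 4 (0.0963), treated wild-type replicates 2 (0.0881) and 4 (0.082), mutant replicates 1 (0.0514), 3 (0.06) and 4 (0.0523) and untreated replicate 3 (0.0505). With antibiotics 11 of 28 lists passed, 0 with an estimated correlation. Inflammatory lists did not pass with all arrays: NF-kB targets had 1 of 14 higher and 1 lower (0.812), TLR4 signalling genes 1 of 18 higher and 1 lower (2 and 1 adjusted over the list alone; 0.224), acute-phase proteins 3 of 28 higher (0.19) and interferon-stimulated genes 6 of 30 lower (7 adjusted over the list alone; 0.176). The acute-phase list passed without antibiotic replicate 1 (0.0446) or treated wild-type replicate 3 (0.0369), and the interferon list without treated wild-type replicate 1 (0.035). Further lists that did not pass were p53 targets (1 of 21 higher and 2 lower, 0.228, but 0.044 with no filter), oncofetal markers (1 of 13 lower, 0.499), pericentral genes (4 of 21 higher and 2 lower, 5 and 2 adjusted over the list alone, 0.167, but 0.0416 without treated wild-type replicate 2) and cytochrome P450 genes (5 of 27 higher and 6 lower, 7 and 10 adjusted over the list alone, 0.518), the last 2 with Cyp3a11, open to cross-hybridisation, at -1.92 ± 0.29.

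The antibiotic and mutant groups were then compared directly, which tests where the 2 effects differ. Most endothelial, macrophage and matrix genes were higher with antibiotics than in the mutant. The growth factor gene Hgf was 2.06 ± 0.23 higher (6.51 ± 0.38 against 4.45 ± 0.48, adjusted p = 0.000104), Vsig4 3.12 ± 0.45 higher (0.000794) and Stab1 1.42 ± 0.16 higher (0.000136). Sult1e1 (4.8 ± 0.64), Cyp4a14 (4.44 ± 0.73) and G6pc (3.4 ± 0.6) were also higher, while Slco1a1 (-3.58 ± 0.62) and Abcc4 (-1.56 ± 0.4) were lower. In all, 1165 genes differed, 652 higher and 513 lower with antibiotics (56% higher), and arrays did not overlap for 1477 genes (15.6%, against 2.9% by chance). The count was 723 without mutant replicate 1, 757 without antibiotic replicate 3, and 673 with the fit held to both groups alone.

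By list, 14 of 28 passed the camera test, 10 higher and 4 lower with antibiotics, and 0 with an estimated correlation. Of 17 endothelial genes, 15 were higher with antibiotics (16 adjusted over the list alone; median 0.98, camera adjusted p = 2.45e-12; adjusted p = 0.185 with an estimated correlation). The same held for 15 of 16 macrophage genes (16 adjusted over the list alone; median 1.62, camera adjusted p = 7.29e-16; adjusted p = 0.118 with an estimated correlation) and 20 of 32 matrix genes (24 adjusted over the list alone; median 1.05, camera adjusted p = 8.24e-15; adjusted p = 0.185 with an estimated correlation). Fatty acid oxidation genes were higher for 9 of 31 members (12 adjusted over the list alone; median 0.43, camera adjusted p = 1.06e-06; adjusted p = 0.398 with an estimated correlation). The 4 lower lists were male-biased genes with 10 of 16 (13 adjusted over the list alone; median -0.92, camera adjusted p = 3.11e-08; adjusted p = 0.185 with an estimated correlation), NRF2 targets with 8 of 27 (13 adjusted over the list alone; median -0.42, camera adjusted p = 4.48e-05; adjusted p = 0.185 with an estimated correlation), cholesterol biosynthesis with 4 of 20 (10 adjusted over the list alone; median -0.52, camera adjusted p = 6.17e-06; adjusted p = 0.393 with an estimated correlation) and stress response genes with 3 of 25 (median -0.2, camera adjusted p = 0.00524; adjusted p = 0.398 with an estimated correlation). The other higher lists were monocyte-derived macrophages (7 of 17, 11 adjusted over the list alone; camera adjusted p = 2.06e-05; 0.185 with an estimated correlation), oncofetal markers (6 of 13, or 9 higher and 1 lower adjusted over the list alone; 2.2e-05 and 0.118), p53 targets (7 of 21 and 1 lower, 9 and 1 adjusted over the list alone; 0.000118 and 0.292), replication (2 of 39 and 1 lower, 1 and 1 adjusted over the list alone; 0.00219 and 0.613, and 0.253 with fry) and growth factors (5 of 17 and 2 lower, 7 and 2 adjusted over the list alone; 0.047 and 0.185). No mitosis gene differed at the adjusted threshold (0 of 39, also over the list alone). The mitosis list still lay higher by a median of 0.61 (camera adjusted p = 0.000182, but 0.613 with an estimated correlation and 0.279 with fry). The kinase Ttk was at 1.28 ± 0.47 (adjusted p = 0.0912).

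**Figure D3:**
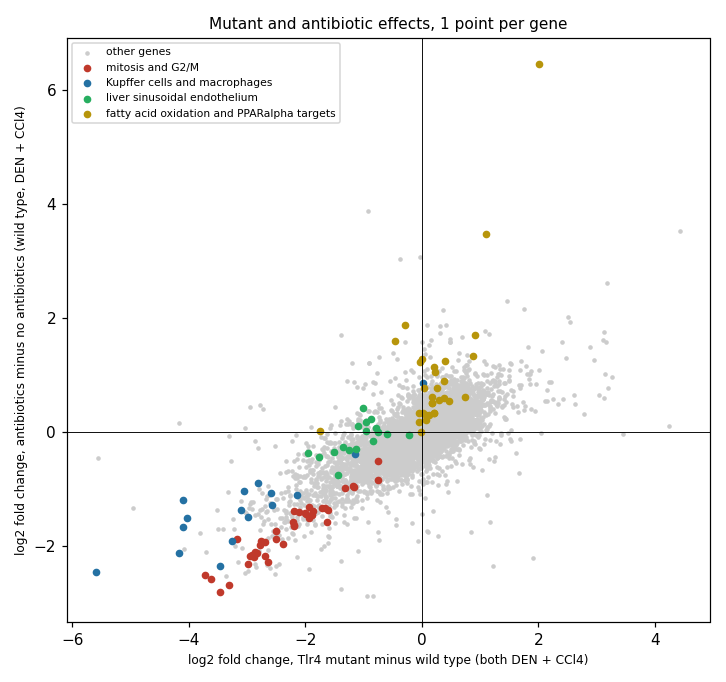
Log2 fold change of each of 9482 genes (points) in treated mutant against treated wild type (horizontal axis) and in the antibiotic group against treated wild type (vertical axis), with 4 gene lists coloured. Mitosis genes lie low on both axes (medians -2.22 and -1.65), endothelial genes lie left of 0 at a median of -1.01 but near 0 vertically (median -0.06), and both axes share the same treated wild-type arrays.

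The overlap of the mutant and antibiotic effects was counted gene by gene. Of the 1668 genes lower in the mutant and the 854 lower with antibiotics, 659 were lower in both (150 if independent), and they held 36 of 39 mitosis genes, 14 of 16 macrophage genes, 16 of 32 matrix genes, 9 of 39 replication genes and 1 of 17 endothelial genes. Of the 1249 and 469 higher genes, 276 were higher in both (61.8 if independent; 505 after quantile normalization and 508 with arrays weighted), with 4 fatty acid oxidation and 4 stress response genes. Only 4 genes were called in opposite directions, Clca3a1, Cyp2c37, Ecm1 and Pomgnt2, named after their values were seen. Both effects use the same treated wild-type arrays, which alone makes them correlate. The correlation across genes, which are not independent replicates, was 0.721, against a mean of 0.502 and a highest of 0.532 in 100 simulations of unchanged groups, and the covariance was 0.226 against 0.0194. The simulations drew genes independently, so their narrow range cannot show how far genes that vary together would spread. With the 4 shared arrays divided so that none served both effects, the correlation averaged 0.623 (0.589 to 0.64 over 6 divisions), and 246 genes were lower in both on average (41.8 if independent). Without antibiotic replicate 1, 429 were lower and 147 higher in both, and the second count was also low without treated wild-type replicates 2 (177) or 4 (151).

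The last question is how far each group stood from untreated liver for the genes that treatment changed. Of the 3408 genes raised in treated wild-type mice, 1339 (39.3%) were lower in the mutant and 105 higher, and 673 (19.7%) were lower with antibiotics and 56 higher. Of the 2530 lowered genes, 713 (28.2%) were higher in the mutant and 91 lower, and 257 (10.2%) were higher with antibiotics and 58 lower. The counts of lowered and then higher genes depended on scaling: they were 1077 in the mutant and 397 with antibiotics with each array centred, 1281 and 504 after quantile normalization, and with antibiotics 467 with arrays weighted. The treated wild-type arrays enter both sides, which alone gives an apparent return, so the arrays were again divided: on average 975 raised genes (32.3%) were then lower in the mutant and 266 (8.78%) with antibiotics, and 366 lowered genes (17.2%) were higher in the mutant and 80 (3.74%) with antibiotics. Each effect then rested on fewer arrays, which alone lowers the counts. Among all genes, those lower with antibiotics went from 854 to 330 on average. The covariance with the treatment effect was -0.534 in the mutant and -0.3 with antibiotics, against -0.0192 and -0.0193 in simulated unchanged groups. With the arrays divided it averaged -0.515 and -0.281. The simulations left out the treatment effect too, so their correlation and slope are no measure of no change. The correlation was -0.593 in the mutant and -0.485 with antibiotics (-0.463 in the simulations for both). With the arrays divided, where no array is shared, the means were -0.559 and -0.435. The slopes over treatment-changed genes were -0.296 and -0.168. Those of the simulations (-0.429 and -0.43) were taken over all genes and cannot be set against them. Without antibiotic replicate 1, 431 raised genes were lower and 158 lowered genes higher with antibiotics, and the second count was 163 without treated wild-type replicate 2 and 149 without replicate 4. Against untreated mice, 5136 of all 9482 genes differed in the mutant, where strain differs as well (3095 higher, 2041 lower), and 5577 with antibiotics (3269 higher, 2308 lower). The share higher was 60.3% in the mutant, but 43.4% with each array centred and 47.1% after quantile normalization, and 58.6% with antibiotics, but 44.5% and 45.5%. Macrophage genes in the mutant had a median of -0.36 against untreated, with 6 of 16 lower and 5 higher, whereas with antibiotics the median was 1.37 with 11 higher and 0 lower. Endothelial genes had medians of -0.3 in the mutant, with 5 of 17 lower and 1 higher, and 0.41 with antibiotics, with 7 higher. These values rest on 3 untreated arrays that spread widely. Without untreated replicate 1, a check made after the values were seen, the macrophage medians were -0.56 in the mutant (7 lower, 4 higher) and 1.1 with antibiotics (3 lower, 8 higher), and the endothelial medians were -0.72 (11 lower, 0 higher) and 0.17 (6 higher). Without untreated replicates 2 or 3, 3 endothelial genes were lower in the mutant.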

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

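The tests of a lower share of other cells, of a strain difference without treatment, of genes with a single probe set, of chromosome stretches and of lists without untreated replicate 1 were chosen only after the result was seen.

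The 659 genes lower than treated wild type in both the mutant and the antibiotic group held most mitosis and macrophage genes, and both effects are measured against the same 4 arrays. Shared arrays as the whole cause call for a correlation near 0 once no array serves both effects, but it averaged 0.623 over the 6 divisions (lowest 0.589). Values near background as the cause would leave no correlation among well-detected genes, but over 6041 genes at 6 or more in every group mean it was 0.469 (lowest 0.424). Both values argue against these explanations as the whole cause, and an unrecorded batch of the treated wild-type arrays was not tested, since the labels name none. A response common to loss of Tlr4 function and antibiotics, with less cell division and fewer or altered macrophages, may underlie the overlap, as a hypothesis found and examined on the same data.

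Macrophage, endothelial and matrix genes were all lower in the mutant than in treated wild type, with medians of -3.08, -1.01 and -1.7, and cholangiocyte genes lay at -0.24. A lower share of all cells other than hepatocytes would lower these lists alike, but the macrophage median lay -2.07 from the endothelial one (permutation p = 3e-05 over 16 and 17 members, 100000 permutations), which argues against it as the whole cause. The permutations shuffled members that vary together, so this p does not measure the spread between samples. A loss confined to some cell types, or lower expression within them, stays open. A strain difference present without treatment cannot be told apart from an effect of treatment, because no array holds untreated mutant liver; of 16 macrophage genes, 6 were lower in the mutant than in untreated wild type and 5 higher (7 and 4 without untreated replicate 1). Above untreated levels in the mutant were 13 of 17 monocyte-derived macrophage genes and 19 of 32 matrix genes (11 and 16 without untreated replicate 1). From the first of these counts, resident macrophages may be more affected than recruited ones, a hypothesis whose difference between the lists was not tested. Against it, Ccr2 of the monocyte-derived list was at least 3.71-fold lower in the mutant than in treated wild type. The lists also do not separate resident from recruited cells cleanly. The Kupffer cell and macrophage list holds general macrophage genes such as Adgre1, and the monocyte-derived list holds Lgals3, which is also of injured tissue.

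In the mutant, 29 genes lay apart from all 11 wild-type arrays by a mean of at least 2-fold in the deposited values. Of these, 20 were higher and 9 lower. They were called against each wild-type group, with no call in the treatment or the antibiotic comparison. Arrays that do not overlap arise by chance for 0.147% of genes. That share leaves out the other conditions, so the 29 genes cannot be set against it. Among those named after their values were seen were Slc12a4 (6.14 against 1.99), Sfmbt2 (5.49 against 1.97) and Mndal (3.88 against 8.94). Some lay near background, such as Shroom4 (4.12 against 2.34) and Icam2 (3.32 against 4.34). These 2 differed by less than 2-fold from a floor of 4, as did others such as Pogk (4.77 against 3.63) and D630045J12Rik (4.86 against 3.68). A strain variant under the probes would leave other probe sets of these genes unmoved, but 70% of them (7 of 10) were called the same way. That argues against a variant for the genes of those 7 probe sets only. The remaining probe sets did not follow, so a variant stays open there. Whether probe sets of a gene cover the same stretch of transcript was not examined. For the 20 genes with 1 kept probe set a variant cannot be told apart from a change in transcript level. Stretches of chromosome that differ between the substrains stay open as well: 3 pairs of these genes lay within 10 measured genes of each other, against a median of 1 and a highest of 6 in 10000 random sets (permutation p = 0.0538).

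Single arrays stood far from the other 3 of their group, by a gap (given as a share of the group's range) above Dixon's limit for 4 values, in 13 of 198 groups of 4 arrays, where chance gives about 1 in 20. Treated wild-type replicate 1 was highest for the mean of p53 targets (8.14 against 7.43 to 7.54, gap 0.851) and for Sprr1b (3.04 against 2.33 to 2.39, gap 0.911) and lowest for Sfmbt2 (1.8 against 2.11 to 2.14, gap 0.895). Mutant replicate 3 was lowest for the mean of matrix genes (6.54 against 6.9 to 6.91, gap 0.971), of stress response genes (9.5 against 9.96 to 9.99, gap 0.939) and for Tyrobp (5.21 against 5.67 to 5.69, gap 0.955), and highest for Mndal (6.58 against 2.87 to 3.15, gap 0.923). Mutant replicate 4 was lowest for Top2a (8.15 against 8.66 to 8.73, gap 0.883), and mutant replicate 2 highest for Rgs16 (8.27 against 2.83 to 3.38, gap 0.898). Antibiotic replicate 1 was lowest for the mean of oncofetal markers (8.06 against 8.55 to 8.61, gap 0.889). Antibiotic replicate 2 was lowest for the mean of fatty acid oxidation genes (10.27 against 10.69 to 10.77, gap 0.832) and for Sprr1b (2.81 against 6.98 to 7.4, gap 0.908), and highest for B3galnt1 (7.36 against 6.59 to 6.71, gap 0.84).

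The mutant and antibiotic effects differed by the direct test for 1165 genes. Among 2133 kept probe sets with several gene symbols or none, which the comparisons left out, 1104 (51.8%) were called between treated and untreated wild type, 615 higher and 489 lower. In the mutant 397 (18.6%) were called and with antibiotics 201 (9.4%).

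Regrouping the arrays of each comparison in all 35 ways, with fits on the 2 groups alone, made chance unlikely for the counts of genes, since only the real grouping (1 of 35) called as many. Chance was not excluded, since that share is the smallest 35 groupings can give. Groupings that mix the 2 groups also widen the spread within each. The real counts and the highest of the others were 6091 and 0 for treatment, 2681 and 0 for the mutant, 913 and 1 for antibiotics, 673 and 0 for antibiotics against the mutant, 5280 and 9 for antibiotics against untreated, and 4950 and 3 for the mutant against untreated. For the number of gene lists past the camera test at the preset correlation, chance could not be excluded, so that number alone carries little weight. In the treatment comparison 11 of 35 groupings called as many lists as the real one (17, highest other 20), in the mutant comparison 17 (10, highest other 15) and in the antibiotic comparison 16 (9, highest other 16). The mean shift of a list was largest in the real grouping for 22, 10 and 9 of 28 lists in turn (exact p = 0.0286, the smallest 35 groupings can give), and after adjustment 22, 0 and 0 lists passed 0.05. Lists at that smallest p had adjusted p of 0.0364, 0.08 and 0.0889 in turn. The adjusted value depends on how many lists reach the smallest p. The counts of 0 therefore do not show that list shifts were weaker in the mutant or with antibiotics.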

How the results depend on the processing

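All alternatives were planned, so no tests here were chosen only after the result was seen. No paired analysis was possible because the labels number the arrays from 1 to 15 across the groups and give nothing that links an array of one group to an array of another. Of the named genes 1 reversed, Ikbkg in the mutant (0.74 as reported, -0.31 with probe sets averaged, adjusted p 0.18), and the cause was not tested. The majority of calls turned from higher to lower in treatment (57.4% higher, 42.4% with arrays centred, 43.8% after quantile normalization) and from lower to higher in the mutant (42.8%, 50.5% and 55.3%). Counts outside 1.5 times the value reported follow, and except where fewer arrays, more probe sets tested or a stricter threshold shows it, the cause was not tested. Centring each array gave 1077 genes lowered by treatment and higher in the mutant (713 as reported) and 397 such genes with antibiotics (257). Quantile normalization gave 1281 and 504 of these, and 505 genes higher in both effects (276). Testing every probe set gave 9310 calls in treatment (5938), 4443 in the mutant (2917), 8705 for antibiotics against untreated (5577), 7933 for the mutant against untreated (5136) and 1117 lowered and higher in the mutant. Weighting arrays gave 508 higher in both effects and 467 lowered and higher with antibiotics, and a fit of only the 2 groups gave 673 genes for antibiotics against the mutant (1165). At least 2-fold changes numbered 2664 in treatment, 934 in the mutant, 408 with antibiotics, 359 for antibiotics against the mutant, 2305 and 1913 for antibiotics and the mutant against untreated, 281 lower and 35 higher in both effects, 644 raised and lower in the mutant, 77 lowered and higher, and with antibiotics 277 and 30. Adjusted p under 0.01 left 1690 in the mutant, 413 with antibiotics, 428 between them, 239 lower and 57 higher in both, 313 lowered and higher in the mutant, and with antibiotics 242 raised and lower and 64 lowered and higher. Dividing the treated wild-type arrays left 246 lower and 67 higher in both, 366 lowered and higher in the mutant, and with antibiotics 266 raised and lower and 80 lowered and higher. With an estimated correlation 0, 0 and 0 lists passed in treatment, the mutant and antibiotics (18, 10 and 11 as reported). Leaving out each array in turn gave 5335 to 5973 genes in treatment, 2244 to 2952 in the mutant and 820 (without antibiotic replicate 1; 838 without treated wild-type replicate 4) to 1624 (without antibiotic replicate 2) with antibiotics. It gave 723 (without mutant replicate 1; 757 without antibiotic replicate 3) to 1375 for antibiotics against the mutant, and 4978 to 5634 and 4406 to 5185 for antibiotics and the mutant against untreated. Counts lower in both effects ran from 429 (without antibiotic replicate 1) to 740, and higher in both from 147 (without antibiotic replicate 1; 151 and 177 without treated wild-type replicates 4 and 2) to 391. Raised genes lower in the mutant ran from 1136 to 1359, lowered and higher from 494 to 721. With antibiotics these ran from 431 (without antibiotic replicate 1) to 752 and from 149 (without treated wild-type replicate 4; 158 without antibiotic replicate 1, 163 without treated wild-type replicate 2) to 350. Lists ran from 17 to 18, 10 to 12 and 9 to 13. Over all arrays left out, 302 of 4095 calls of named genes ended and 3793 were kept, with 6 gained among 285 results not called, and 16 of 585 list calls ended and 569 were kept, with 13 gained among 675. Of 273 calls of named genes, 30 ended in a fit of only the 2 groups, 18 with no filter, 11 with values under 4 set to 4, 8 with probe sets averaged, 7 after quantile normalization, 6 with arrays weighted, 3 with arrays centred and 0 with a trended robust prior, and 1 of 224 under a stricter filter. Of 39 list calls, 39 ended with an estimated correlation, 6 after quantile normalization, 3 in a fit of only the 2 groups, 3 under a stricter filter, 2 with arrays centred, and 1 each with probe sets averaged, no filter, fry or values set to 4, while fry added 9 calls and no filter 7. Lists in the comparison of antibiotics with the mutant were run only with an estimated correlation and fry. Signal over background limits the arrays, since 34.6% to 36.7% of probe sets reached 4 and genes below that were not compared.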

Other observations

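The tests of heat shock, immediate early and single epithelial stress genes, and of a uniform loss of dividing cells, were chosen only after the result was seen.

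Some genes of stressed epithelium, picked because they stood high in the mutant, can be given as values only and say nothing about how common such a rise is. Sprr1a, a cornified envelope protein, rose from 7.78 ± 0.73 to 10.95 ± 0.73 in the mutant (3.17 ± 0.45, adjusted p = 0.000143) and to 10.39 ± 0.9 with antibiotics (2.61 ± 0.45, 0.00325). Cpe, a peptide processing enzyme, rose from 6.3 ± 0.35 to 9.45 ± 1.08 in the mutant (3.16 ± 0.44, 0.00013) and to 7.88 ± 0.72 with antibiotics (1.58 ± 0.44, 0.0294). Slc3a2, a subunit of amino acid carriers, rose in the mutant from 7.55 ± 0.25 to 9.32 ± 0.7 (1.77 ± 0.29, 0.000437), and it was lower with antibiotics than in the mutant (-1.32 ± 0.29, 0.00962). With antibiotics, the call of Phgdh (1.76, adjusted p = 0.0438) ended without any 1 of 10 arrays, which were antibiotic replicates 1 (0.0991), 3 (0.058) and 4 (0.129), treated wild-type replicates 2 (0.126), 3 (0.0713) and 4 (0.0846), mutant replicate 4 (0.0539) and untreated replicates 1 (0.0535), 2 (0.0556) and 3 (0.0553). It also ended with probe sets averaged (0.0686), no filter (0.0608) and a fit of only the 2 groups (0.0576).

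Among 9 heat shock genes, 6 rose with treatment (median 0.53), 4 were higher in the mutant than in treated wild type and 1 with antibiotics, and 3 were lower with antibiotics than in the mutant. Hspa1b, an inducible chaperone, rose from 9.02 ± 0.79 to 11.9 ± 0.58 in the mutant (2.88 ± 0.4, adjusted p = 0.000117) and to 10.52 ± 0.66 with antibiotics (1.5 ± 0.4, 0.0232), and Hspb1 rose in the mutant from 6.51 ± 0.88 to 9.55 ± 1.04 (3.04 ± 0.64, 0.00249). Among 11 immediate early genes, 6 rose and 2 fell with treatment (median 1.92), with Fos up by 3.9 ± 0.48 (6.66e-06) and Myc down (-2.26 ± 0.35, 6.46e-05). The early gene Ier3 rose further in the mutant, from 6.29 ± 0.35 to 8.81 ± 1.06 (2.51 ± 0.4, 0.000345), and with antibiotics to 8.31 ± 0.26 (2.01 ± 0.4, 0.00623). Btg2 was higher with antibiotics than in the mutant (9.99 ± 0.24 against 7.94 ± 0.19, 0.000968). Sprr1a, Cpe, Slc3a2, the heat shock genes named here, Fos, Myc and Ier3 were not run under the alternatives.

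Mitosis genes kept less of their treatment rise than replication genes in the mutant. On the linear scale the medians were 14.2% over 39 mitosis genes and 51.3% over 38 replication genes, a difference of -37 (permutation p = 1e-05, the smallest the permutations can give). With values under 4 set to 4 they were 10.6% and 49.8%, and with antibiotics, as deposited, 26.1% and 64.8% (difference -38.7, the same p). On the log2 scale the medians were 52.9% and 77.5% in the mutant and 65.6% and 88.7% with antibiotics. The permutations shuffled genes that vary together, so their p does not measure the spread between samples. A uniform loss of dividing cells would leave equal linear shares of both lists if signal is proportional to transcript and both rises come from dividing cells alone. Neither condition was tested. Only where they hold does the size of the difference, rather than its p, argue against such a loss as the whole cause. A candidate explanation is that cells entered S phase but fewer went on to mitosis at the time of sampling, a hypothesis that was not tested here.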
